A study of Mus musculus with 10 samples.

How the data were processed

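Gene expression was measured in whole kidneys of 5-week-old mice on Affymetrix whole-transcript arrays, which carry probes along the length of each transcript. The 10 arrays came from 5 control mice and 5 mice with a tubule-specific knockout of Lkb1 (gene symbol Stk11), per the labels' protocols. Sense cDNA was made from 500 ng of total RNA, fragmented and labelled with biotin, per the labels' protocols. The knockout was made by crossing mice with a floxed Lkb1 allele to KspCre mice, which carry the Cre recombinase under the promoter of Cdh16, a cadherin of kidney tubules. Controls were littermates without the Cre transgene that carried the floxed allele on 1 or both chromosomes. Only the knockouts thus carried Cre, so effects of the transgene itself cannot be told apart from those of Lkb1 loss.

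Some labels conflict. The titles call the second group a knockdown, whereas the growth protocol describes a Cre knockout, and the text here follows the protocol. The design text of the series speaks of MDCK cells, a dog kidney cell line, whereas every sample analysed here is mouse kidney. The strain label is C57Bl/6N, whereas the protocol gives a mixed background for the floxed mice. The sex of the mice is not in the labels.

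The deposited values are log2 expression values per transcript cluster made by RMA (robust multi-array average), per the submitters' processing notes. RMA corrects the background, normalises the arrays to a shared distribution and summarises the probes of each transcript cluster, so a deletion of some exons is averaged with the exons that remain. The genome build is mm10, per the submitters' processing notes. The versions of the software and any filters are not given in the sources used here. That the values are on a log2 scale was taken from their range, with array medians from 5.35 to 5.42 and array maxima from 14.07 to 14.28. Arrays carry no count of reads, so the number of arrays limits the precision. The area under the curve separating 1324 positive from 5222 negative control probe sets was 0.888 to 0.900 over the 10 arrays, and correlations between arrays over all genes were 0.992 to 0.998.

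The table held 72688 rows, of which 65770 were transcript clusters and 6918 were control or unmapped rows. Rows were named through the annotation of the array platform, with symbols updated through Entrez identifiers for 1135 rows. A single gene symbol was found for 30604 rows, several for 2146 and none for 39938. Rows with several symbols or none were left out of the gene-level fit. A gene's value was the mean of its rows, which gave 30063 genes, 429 of them with several rows. Coordinates are from the RefSeq annotation of the mm10 build.

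Knockouts were compared with controls with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). The test was two-sided and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. No dim genes were filtered out and no covariate was used. Differences are knockout minus control in log2 units, with the standard error of the fit. Stk11 and Ccl2 were also tested with a two-sided exact permutation test of 5 against 5 values, whose smallest possible p is 0.00794. Of 113 named genes, 7 had a control mean that exceeded less than 50% of the negative control probe sets. Where such a gene, or Cd4, whose control mean exceeded 52.3%, is given a fold it is a bound, "at least", with values below an array's median of those probe sets (5.10 to 5.37) set to that median. This step was added after the data were seen. Tables were joined with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

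Before the data were examined, 30 lists of marker and pathway genes were fixed from textbook kidney biology, the Cre line and the title of the series. A further list of sex chromosome genes was used only as a check of the animals' sex. No list was chosen on the values of these samples. The title names Lkb1, a ciliopathy complex and inflammation, so lists on these subjects are not independent of what the submitters reported. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 30 lists. They were tested again with an estimated correlation and with fry. An exact permutation test of each list's mean per kidney was added after the data were seen.

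Named genes followed a rule fixed before the data were examined. It took Stk11 and Ccl2. It took the 10 largest increases and the 10 largest decreases among genes past the threshold whose 5 knockout values all lay beyond all 5 control values. Predicted genes, small RNA genes and sex chromosome genes were left out of that part. From each list it took up to 4 members past the threshold with the largest differences, or the 2 with the smallest p where none passed. It also took the 4 brightest members of any erythrocyte, adipocyte, adrenal or urothelium list that passed camera.

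The fit was tested on simulated data for the knockout against control comparison, with 200 of 30063 genes changed. It recovered 32% of the genes changed by 0.25 log2 units, 78% of those changed by 0.5, 98% of those changed by 1 and 100% of those changed by 2. Of 164 calls, 10 were false. In the simulated list test the shifted list was called and 0 unshifted lists were called. Genes were simulated as independent, whereas the estimated correlation within the real lists reached 0.71 (macrophage list). The simulation therefore cannot show how often camera calls unshifted lists of correlated genes.

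Alternatives were quantile normalisation of the deposited values, alignment of the array medians, leaving out genes below the 25th or 50th percentile of mean expression, and the brightest row per gene. Other alternatives were eBayes without a trend or with robust estimation, array weights, the replicate number as a block, stricter thresholds and leaving out each kidney in turn. A covariate for sex was planned only if both sexes were present, and was not run.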

Results

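Whole-kidney RNA was profiled from 5 control mice and 5 mice lacking Lkb1 in the kidney tubules, all 5 weeks old. Lkb1, encoded by Stk11, is a kinase that activates AMPK and related kinases. Values are RMA log2 expression values for 30063 genes, each kidney measured on its own array. The title of the series links Lkb1 to a ciliopathy complex and to inflammation, and the comparison asks which genes differ between knockout and control kidneys. All 10 kidneys had a low signal for Xist (4.05 to 4.23), which is expressed from the inactive X chromosome, and a high signal for the Y-linked gene Uty (8.12 to 8.32).

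Stk11, the targeted gene, was lower in all 5 knockouts than in all 5 controls. It lies on chromosome 10 at 80115767 to 80130679 (mm10). The controls 1 to 5 measured 9.43, 9.40, 9.48, 9.46 and 9.40, and the knockouts 1 to 5 measured 9.12, 9.21, 9.07, 9.21 and 9.31. The group means were 9.43 ± 0.03 and 9.18 ± 0.10 (SD, n = 5 each), a log2 difference of -0.25 (SE 0.05, adjusted p = 0.00746). That is 84.1% of the control level (95% interval 78.3% to 90.3%), and the exact permutation p was 0.00794, the smallest this design allows. The array gives a single value for the whole transcript cluster in a whole kidney, so deleted exons were not measured apart from remaining exons, nor tubule cells apart from other cells.

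Knockout kidneys had higher levels of many complement, matrix, phagocyte and tubular injury genes, and lower levels of many genes of the distal nephron and of intercalated cells. As lists, none of these passed camera with an estimated correlation between genes (smallest adjusted p = 0.0571). Grem1, a secreted antagonist of bone morphogenetic proteins, had the largest log2 difference, from 5.07 ± 0.25 to 8.99 ± 0.89 (SD, n = 5 each), which is at least 13.2-fold (log2 difference 3.92, SE 0.33, adjusted p = 7.04e-05). It was followed by the terminal complement component C7 (6.71-fold), the matrix protein gene Dpt (5.30-fold) and the lysozyme gene Lyz2 of myeloid cells (5.19-fold). Lyz1, a near-identical neighbour of Lyz2 named here after its values were seen, was 3.39-fold higher, and signal shared between the pair makes the value of each uncertain.

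The other genes among the 10 largest increases were Serpina3n, Bmp3, Lcn2, Mmp7, Stc1 and Vcam1. Serpina3n, an acute-phase protease inhibitor, was 4.58-fold higher, and the secreted ligand Bmp3 was 4.57-fold higher. Lcn2, a secreted marker of tubular injury, rose from 6.55 ± 0.14 to 8.68 ± 0.36 (log2 difference 2.14, SE 0.14, adjusted p = 1.12e-05). Mmp7, a matrix metalloproteinase, was at least 3.12-fold higher, the secreted glycoprotein gene Stc1 was 4.08-fold higher and the adhesion molecule Vcam1 was 3.48-fold higher.

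Among the 10 largest decreases, Tmem207 fell most, from 8.73 ± 0.21 to 6.76 ± 0.35 (log2 difference -1.97, SE 0.15, adjusted p = 3.06e-05), with controls 3.90-fold above knockouts. The glutathione peroxidase gene Gpx6 differed by -1.56 (SE 0.25) and Wfdc15b by -1.45 (SE 0.13). Slc26a4, the pendrin anion exchanger of intercalated cells, fell from 9.16 ± 0.23 to 8.03 ± 0.48 (adjusted p = 0.00440). Lrrc66, Lrrc31, Malrd1, Tldc2, the proprotein convertase gene Pcsk6 and Egfl6 made up the rest, with log2 differences from -1.17 to -1.07.

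Past the threshold, 1614 genes were higher and 803 were lower in the knockouts, so 66.8% of the calls were increases. The increases also held more large changes: 312 genes were at least 1.5-fold higher and 55 at least 1.5-fold lower, and 91 were at least 2-fold higher against 12 lower. The groups did not overlap for 2580 genes (8.58% of all genes, where chance gives 0.794%), and 1853 of these were among the calls. After quantile normalisation of the deposited values the calls were 1623 higher and 1301 lower, so 55.5% were increases.

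**Figure D1:**
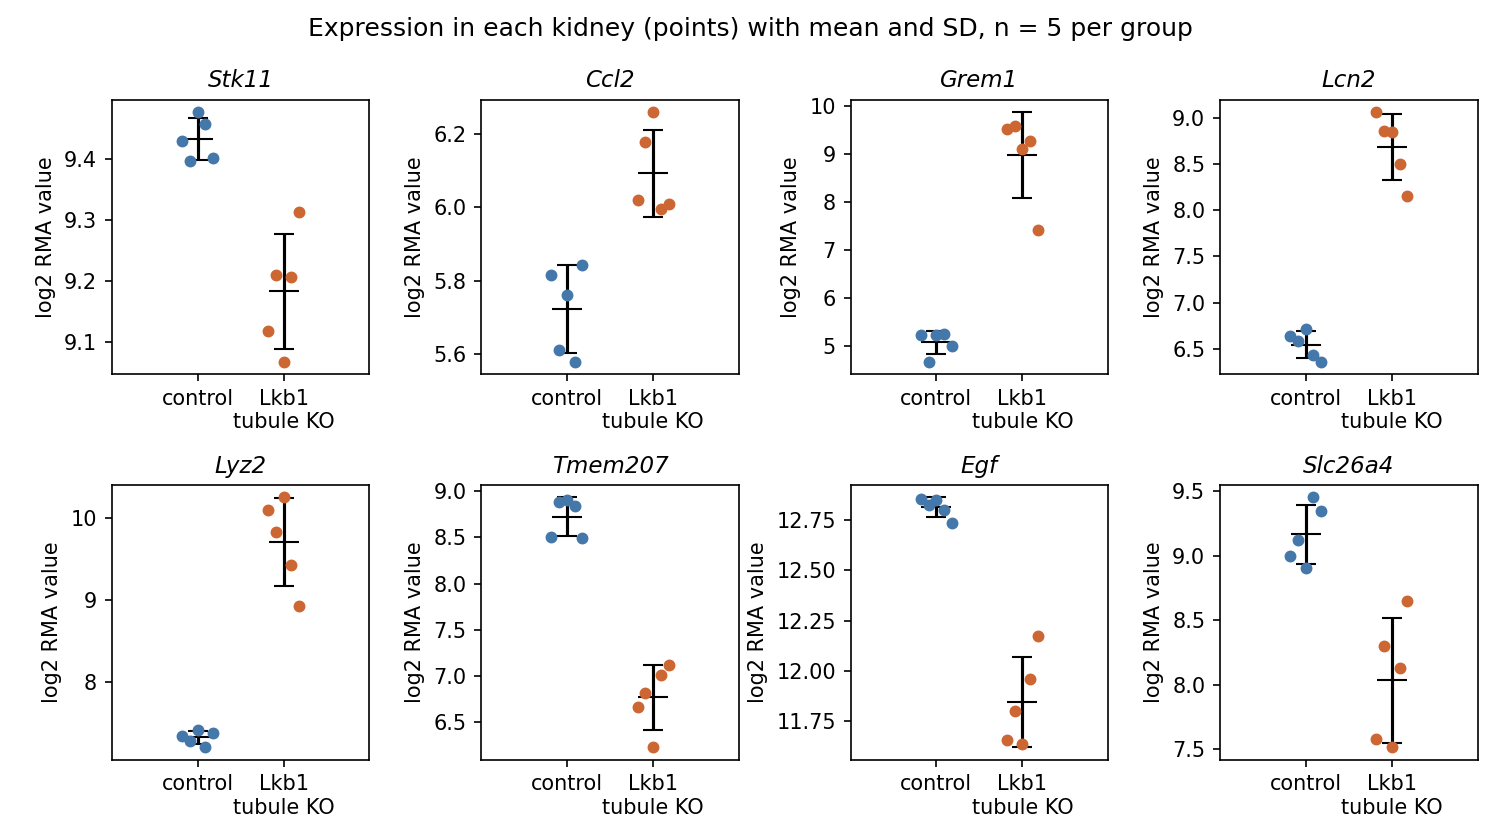
RMA log2 values (y axis) of 8 genes in each kidney, for 5 controls and 5 Lkb1 tubule knockouts (x axis), with points for kidneys, a bar for the mean and whiskers for the SD. Grem1 rises from a mean of 5.07 to 8.99, with knockout replicate 5 at 7.42, and Stk11 differs by -0.25.

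Most phagocyte markers and some chemokine genes were higher in the knockouts. Of 29 measured macrophage and mononuclear phagocyte markers, 26 rose, 0 fell and 3 did not pass (28 rose when adjusted over the list alone), with a median log2 difference of 0.87. Apart from Lyz2, the pore-forming protein gene Mpeg1 was 2.78-fold higher, the mannose receptor gene Mrc1 2.65-fold and the protease gene Ctss 2.48-fold. This list had adjusted p = 0.0852 with an estimated correlation. Of 37 chemokine and cytokine genes, 15 rose, 0 fell and 22 did not pass (20 rose when adjusted over the list alone), also with adjusted p = 0.0852 with an estimated correlation. Ccl2, the chemokine that attracts monocytes, rose from 5.72 ± 0.12 to 6.09 ± 0.12 (SD, n = 5 each), a log2 difference of 0.37 (SE 0.07, adjusted p = 0.00734, exact permutation p = 0.00794). It lies on chromosome 11 at 82035577 to 82037452. The signal of Ccl2 was dim: its control mean exceeded 61.4% of the negative control probe sets and its knockout mean 70.2%. The control mean of Ccl9 exceeded 62.1% of them, so the sizes of both changes are uncertain. Larger rises were seen for Ccl9 (2.12-fold), the alarmin Il33 (1.84-fold), the macrophage growth factor gene Il34 (1.64-fold) and Ccl5 (1.62-fold).

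Some NF-kappaB targets, complement genes and interferon response genes also rose. Among 19 NF-kappaB target genes, 11 rose, 1 fell and 7 did not pass (13 and 1 adjusted over the list alone; adjusted p = 0.0968 with an estimated correlation). Birc3, an inhibitor of apoptosis, was 1.60-fold higher, the TNF receptor gene Tnfrsf1b 1.53-fold, the adhesion molecule Icam1 1.45-fold and the NF-kappaB inhibitor Tnfaip3 1.43-fold. The member that fell, named after its values were seen, was Sod2 (log2 difference -0.17). Of 14 complement genes, 9 rose, 0 fell and 5 did not pass (10 rose when adjusted over the list alone; adjusted p = 0.0852 with an estimated correlation). Besides C7 these included Cfi (2.67-fold), Serping1 (2.33-fold) and the receptor gene C3ar1 (1.84-fold). Of 31 interferon response genes, 8 rose, 0 fell and 23 did not pass (12 rose when adjusted over the list alone; adjusted p = 0.176 with an estimated correlation), led by Bst2 (1.52-fold) and Gbp2 (1.35-fold).

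Some T and NK cell markers rose, while no B cell or granulocyte marker passed. Among 20 T and NK cell markers, 4 rose, 0 fell and 16 did not pass (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.515 with an estimated correlation). Cd3e was 1.26-fold higher, Cd4 at least 1.88-fold and Il7r at least 1.09-fold. Klrd1 (3.72 and 4.14) was below the median of the negative control probe sets in both groups, so it has no fold here. None of the 14 B and plasma cell markers and none of the 14 neutrophil and granulocyte markers passed by limma, with 0 in either direction adjusted over the list alone. In each list 2 members were higher and 0 lower at an unadjusted p under 0.05, and neither list passed camera (adjusted p = 0.448 and 0.332). The smallest p among them belonged to Ighm (log2 difference 0.45, adjusted p = 0.0955) and Ly6g (0.23, adjusted p = 0.0820).

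Most matrix genes and most injury genes on the lists also rose. Of 34 fibroblast and extracellular matrix genes, 27 rose, 0 fell and 7 did not pass (32 rose when adjusted over the list alone; adjusted p = 0.0852 with an estimated correlation), with a median log2 difference of 0.63. The proteoglycan Lum was at least 2.47-fold higher, fibronectin (Fn1) 2.58-fold, periostin (Postn) 2.57-fold and decorin (Dcn) 2.52-fold. Of 34 tubular injury genes, 21 rose, 1 fell and 12 did not pass (28 and 1 adjusted over the list alone; adjusted p = 0.0571 with an estimated correlation). Krt19, a keratin of simple epithelia, was 2.80-fold higher, beside the rises of Lcn2, Mmp7 and Vcam1. The member that fell, named after its values were seen, was the integrin gene Itgb6 (log2 difference -0.56). Among 12 urothelium markers, 7 rose, 0 fell and 5 did not pass (8 rose when adjusted over the list alone; adjusted p = 0.108 with an estimated correlation). The uroplakin genes Upk1b and Upk1a were 2.63-fold and 1.57-fold higher, Upk2 differed by 0.58 in log2 units and Ivl was at least 1.31-fold higher. Relative to the control mean, the mean of this list was 0.30 in control 4 and -0.31 in control 5, with the knockouts at 0.24 to 0.51. The adipocyte list also had its highest and lowest control means in these kidneys (0.42 and -0.34). Psca (log2 difference 0.31, SE 0.25) and Upk3b (-0.10, SE 0.14), which with Upk1b and Upk1a are the brightest members, did not pass.

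Most intercalated cell markers fell, while most principal cell markers did not pass. Of 20 intercalated cell markers, 14 fell, 1 rose and 5 did not pass (15 and 1 adjusted over the list alone; adjusted p = 0.0962 with an estimated correlation), with a median log2 difference of -0.40. Slc26a4 was joined by the water channel Aqp6 (log2 difference -0.94) and the anion exchanger Slc4a1 (-0.74). The carbonic anhydrase gene Car15 was the member that rose, from 10.77 ± 0.07 to 11.99 ± 0.15 (2.33-fold, SE 0.07 in log2 units, adjusted p = 4.04e-06). Of 23 principal cell markers, 4 rose, 2 fell and 17 did not pass (4 and 3 adjusted over the list alone), and this list did not pass camera (adjusted p = 0.152). Its median was -0.01 while its mean was 0.14 and camera's direction was up. By fry for changes in either direction the list passed (adjusted p = 1.56e-07). Besides Stc1, the vasopressin-regulated water channel Aqp2 was 1.92-fold higher and Aqp3 1.45-fold, whereas the sodium channel subunit Scnn1a differed by -0.39. The remaining calls, named after their values were seen, were Hoxb7 (0.25) and Avpr1a (-0.27).

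Of 19 thick ascending limb markers, 11 fell, 1 rose and 7 did not pass (the same counts adjusted over the list alone; adjusted p = 0.0968 with an estimated correlation), with a median log2 difference of -0.38. Egf, the growth factor precursor made in the distal nephron, fell from 12.81 ± 0.05 to 11.85 ± 0.22 (log2 difference -0.96, SE 0.09, adjusted p = 1.04e-04). The prostaglandin receptor Ptger3 differed by -0.86, the calcium-sensing receptor Casr by -0.62 and the chloride channel subunit Bsnd by -0.50. The member that rose, named after its values were seen, was Cldn16 (0.45). Among 17 distal convoluted and connecting tubule markers, 8 fell, 0 rose and 9 did not pass (11 fell when adjusted over the list alone; adjusted p = 0.108 with an estimated correlation). These included Slc16a7 (-0.82), parvalbumin (Pvalb, -0.66), calbindin (Calb1, -0.54) and the sodium-calcium exchanger Slc8a1 (-0.53).

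Some proximal tubule markers fell. Of 31, 7 fell, 0 rose and 24 did not pass (8 fell when adjusted over the list alone; adjusted p = 0.515 with an estimated correlation). The phosphate transporter Slc34a3 differed by -0.61, Slc7a13 by -0.54, the glucose transporter Slc5a2 by -0.46 and the dicarboxylate transporter Slc13a3 by -0.42. Of 18 sexually dimorphic kidney genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone), with Abcc3 at 0.81, Slc7a13 at -0.54 and Slc22a12 at -0.36, and the list did not pass camera (adjusted p = 0.341).

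**Figure D2:**
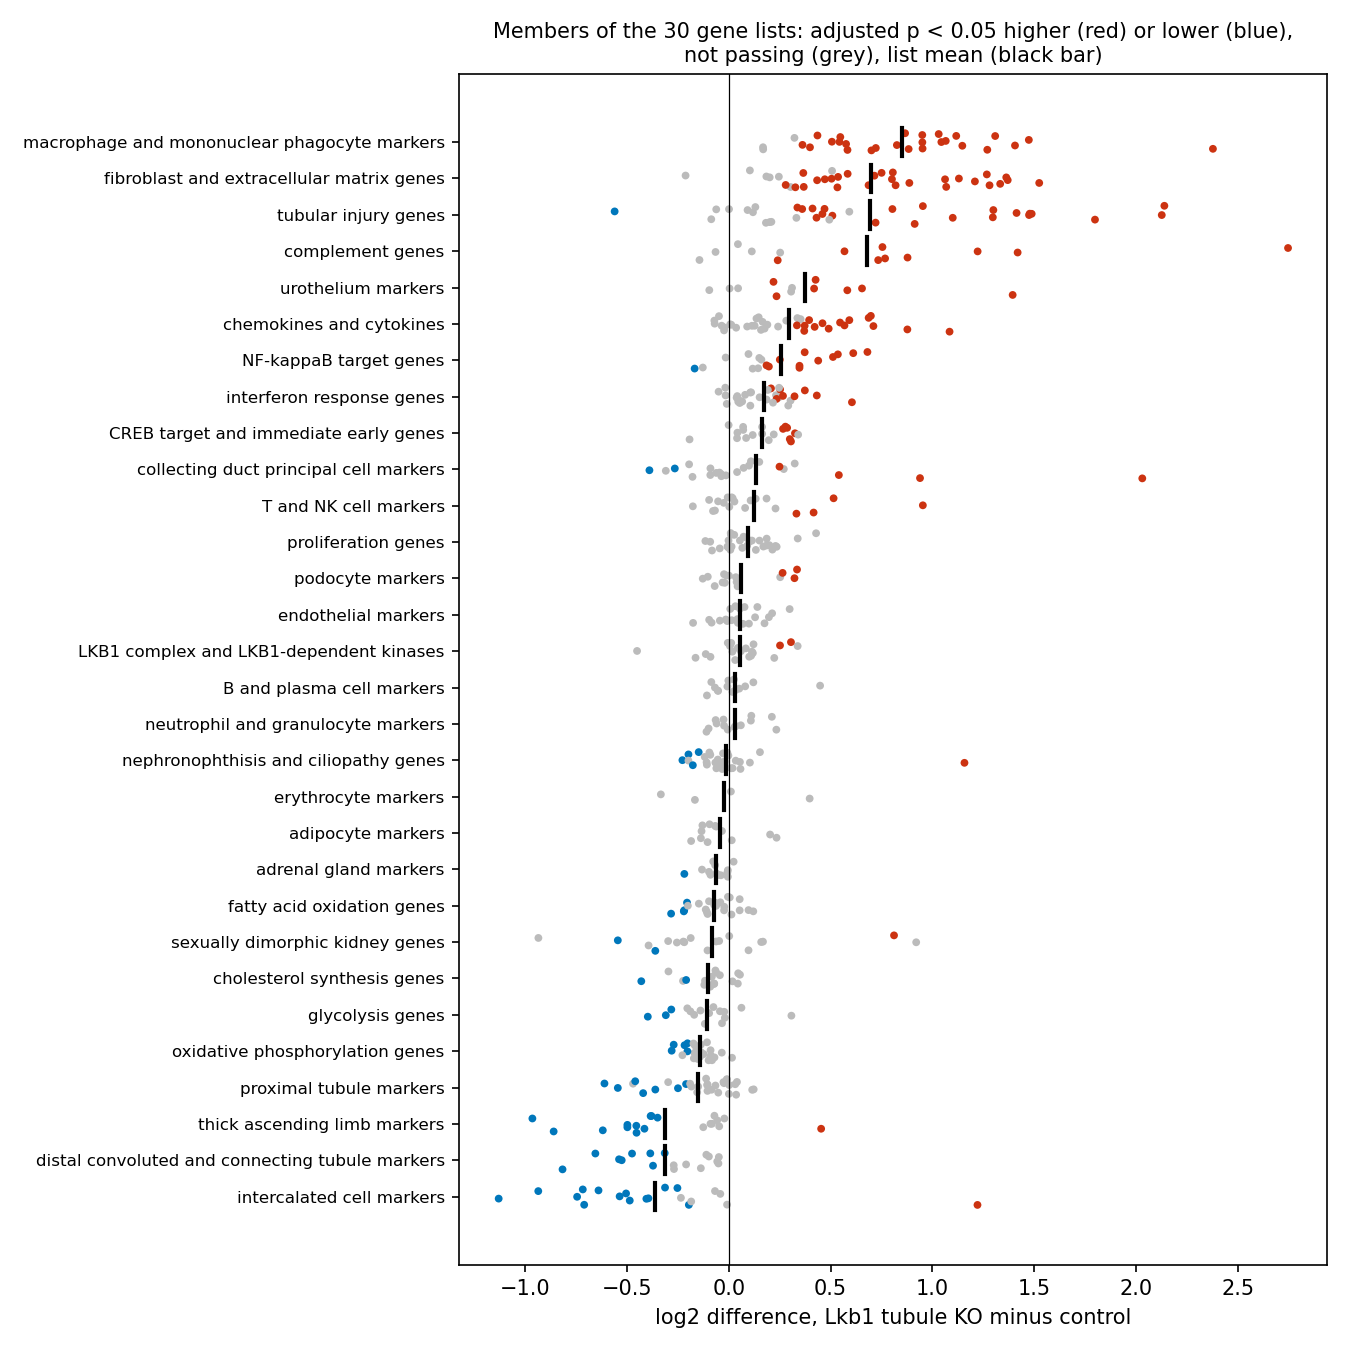
Log2 differences, knockout minus control (x axis), of the members of 30 gene lists (y axis), with points for genes, red and blue for adjusted p under 0.05, grey for the rest and a black bar for the list mean. Means run from -0.36 for intercalated cell markers to 0.85 for macrophage markers.

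Some metabolic genes were lower, while most did not pass. Of 28 oxidative phosphorylation genes, 6 fell, 0 rose and 22 did not pass (18 fell when adjusted over the list alone; adjusted p = 0.288 with an estimated correlation), with a median log2 difference of -0.15. The complex I subunit genes Ndufs1 (-0.28), Ndufa9 (-0.27), Ndufb5 (-0.22) and Ndufv1 (-0.20) were among them. Of 24 fatty acid oxidation genes, 4 fell and 0 rose (also 4 adjusted over the list alone; adjusted p = 0.593 with an estimated correlation), namely Hadhb (-0.28), Acadvl (-0.22), Hadha (-0.22) and Acads (-0.21). Among 16 glycolysis genes, 3 fell and 0 rose (6 fell and 1 rose when adjusted over the list alone; adjusted p = 0.465 with an estimated correlation), namely Pfkm (-0.40), Hk1 (-0.31) and Pfkl (-0.28). Of 18 cholesterol synthesis genes, 2 fell and 0 rose (3 fell when adjusted over the list alone; adjusted p = 0.515 with an estimated correlation), Idi1 (-0.43) and Lss (-0.21).

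Some genes tied to LKB1 kinases and CREB rose, and a few ciliopathy genes passed in either direction. The LKB1 and CREB lists passed camera upward (adjusted p = 0.00916 and 3.63e-07), and neither held with an estimated correlation. Among 21 genes of the LKB1 complex and the kinases it activates, 2 rose, 0 fell and 19 did not pass (3 rose when adjusted over the list alone; adjusted p = 0.288 with an estimated correlation). They were the salt-inducible kinase Sik1 (0.31) and the AMPK subunit Prkab1 (0.25). Among 19 CREB target and immediate early genes, 6 rose, 0 fell and 13 did not pass (8 rose when adjusted over the list alone; adjusted p = 0.0852 with an estimated correlation), including Atf3 (0.32), Sik1, Egr2 (0.30) and Nr4a2 (0.29). Of 33 nephronophthisis and ciliopathy genes, 1 rose, 4 fell and 28 did not pass (1 and 5 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.252). The ciliary gene Dcdc2a was 2.23-fold higher (log2 difference 1.16, SE 0.13, adjusted p = 3.27e-04), while Ahi1 (-0.23), Bbs1 (-0.20) and Ift172 (-0.18) were lower. Of 30 proliferation genes, 0 passed by limma in either direction, adjusted over all genes or adjusted over the list alone, with 6 higher and 0 lower at an unadjusted p under 0.05. The list passed camera upward (adjusted p = 0.517 with an estimated correlation). Mki67 differed by 0.43 (adjusted p = 0.0637) and Ccnb2 by 0.34 (adjusted p = 0.0669).

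Markers of other cell types did not pass as lists in the main fit, although the endothelial list passed with the replicate number as a block. Of 15 podocyte markers, 3 rose and 0 fell (4 rose when adjusted over the list alone; camera adjusted p = 0.0665), namely Kirrel (0.34), Thsd7a (0.32) and Plce1 (0.26). None of 21 endothelial markers passed by limma, also with 0 adjusted over the list alone and with 4 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0533), with Kdr at -0.18 and Plat at 0.30. Of 13 adrenal gland markers, Fdx1 (-0.22) fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.135). None of 4 measured erythrocyte markers passed by limma (1 lower adjusted over the list alone and 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.629), with Klf1 at -0.17 and Tfrc at -0.33. None of 12 adipocyte markers passed by limma (0 adjusted over the list alone and 1 higher at an unadjusted p under 0.05; camera adjusted p = 0.936), with Plin4 at 0.23 and Lipe at -0.09. The median and mean of that list were negative (-0.08 and -0.04), while camera's direction was up.

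Of the 30 lists, 20 passed camera at the preset correlation, 12 upward and 8 downward, and 0 held with an estimated correlation, where the smallest adjusted p was 0.0571 and 11 lists had an unadjusted p under 0.05. By fry 14 lists passed. The exact permutation test of list means, two-sided and added after the data were seen, gave 12 lists, 8 up and 4 down, at adjusted p = 0.0238 or 0.0397. Those up were the macrophage, chemokine, matrix, injury, NF-kappaB, complement, interferon and urothelium lists, and those down were the intercalated, thick ascending limb, distal convoluted tubule and oxidative phosphorylation lists. Camera at the preset correlation also gave a median of 13 lists on random splits of the 10 kidneys. Those splits kept part of the difference between genotypes, so 13 is not a count of false calls. Knockout replicate 5 lay nearest to the controls on the first principal component (2.2, where the other knockouts lay at 11.4 to 24.5), and without it 1947 genes were higher and 1473 lower. The count of lower genes was 496 without control 1, 473 without control 3, 513 without knockout 1, 435 without knockout 2 and 437 without knockout 3.

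**Figure D3:**
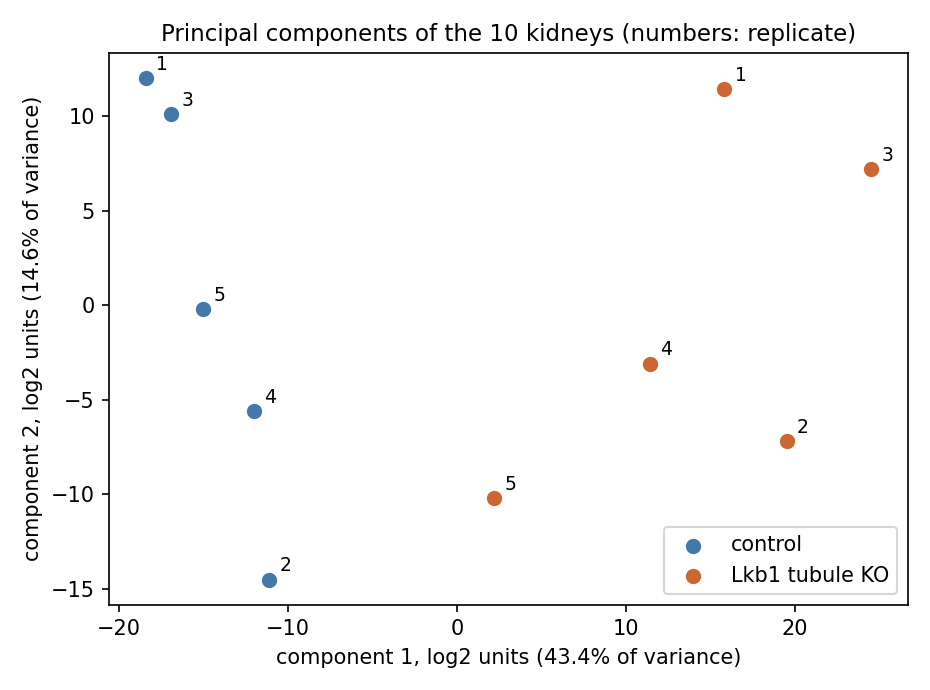
First (x axis, 43.4% of the variance) and second (y axis, 14.6%) principal components of the 10 kidneys over all genes, in log2 units, with each point labelled by its replicate number. Controls lie at -18.4 to -11.1 and knockouts at 2.2 to 24.5 on the first component.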

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

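The tests of knockout replicate 5 for a wrong label, for array quality and among genes of like effect size were chosen only after the result was seen. The counts over splits of the kidneys were planned before the data were examined.

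The gene counts were compared with those of other splits of the 10 kidneys into 5 and 5, with 100 of the 126 possible splits drawn. Only 1 of the 100 splits, the real one, gave as many as 1614 higher genes, and only 1 gave as many as 803 lower genes. A split has no fixed direction, so each count was compared with the larger direction of every other split, of which the highest was 4. Chance is thus argued against for both, at 1 of 100, the smallest share this draw can give. Every other split mixed knockouts with controls, which widens the spread within each side and can lower its counts. The count of gene lists is different: 11 of the 100 splits gave at least the 20 lists of the real split by camera at the preset correlation. Another split gave 23, with 4 knockouts on 1 side. Since 5 knockouts cannot be shared evenly, every other split also kept part of the genotype difference, which can raise its count of lists. This comparison therefore cannot decide the matter, and chance cannot be excluded for that count.

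A kidney lay far from the others of its group in 12 of 286 tests, over 113 genes and 30 gene lists in both groups, no more than the roughly 1 in 20 that chance gives. Among the knockouts, Grem1 was 7.42 in replicate 5, with the others at 9.12 to 9.59. In knockout replicate 3, Aqp6 was 7.23 (others 7.70 to 7.74), Slc7a13 was 10.28 (others 10.53 to 10.62) and Tfrc was 7.95 (others 8.33 to 8.46). In control 5, Pcsk6 was 7.88 (others 8.17 to 8.25) and Hk1 was 8.50 (others 8.69 to 8.76). In the same kidney the mean of the fibroblast and matrix list was -0.17 relative to the control mean (others 0.03 to 0.05), and that of the thick ascending limb list was -0.09 (others 0.01 to 0.04). In control 4, Atf3 was 6.27 (others 6.38 to 6.40) and Upk2 was 6.97 (others 6.43 to 6.58). In control 2, Bank1 was 4.36 (others 4.49 to 4.53) and Ccnb2 was 6.87 (others 6.51 to 6.61).

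Transcript clusters outside the gene table, which have no gene name or several here, also held differences. Of 35331 such clusters 829 passed the threshold (2.35%), 424 higher and 405 lower, compared with 1709 of 30439 clusters with a single name (5.61%).

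Knockout replicate 5, which held the low Grem1 value, lay nearest to the controls, with a macrophage list mean of 0.50, close to knockout 4 at 0.59 and below the other 3 at 0.96 to 1.13. A control labelled as a knockout would keep most called genes within the control range. Yet 59.9% of the 3420 genes called without this kidney lay beyond all 5 controls in it on the called side. Chance gives 16.7% for genes picked without regard to these controls. These genes were called with the same 5 controls, so a mislabelled control could exceed 16.7% by an amount not measured here. Its Stk11 value (9.31) was below every control, although it was the highest of the knockouts (others 9.07 to 9.21). A poor array is argued against by its separation of positive from negative control probe sets, 0.899, where the other arrays gave 0.888 to 0.900. In the planned test of a single common fraction of the effect, the median fraction was 0.521 for genes called higher and 0.304 for genes called lower. The gap was 0.216 (95% bootstrap interval over genes 0.186 to 0.244), which by the plan goes against a common fraction for all called genes. That interval treats the genes of 1 kidney as independent, so it is likely too narrow. Genes called lower had smaller effects (median 0.248 against 0.340), so the planned gap may follow effect size. Among genes changed by 0.5 to 1 the gap was -0.0611 (interval -0.168 to 0.0486). For those genes a milder effect of one size stays open, as does its origin.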

How the results depend on the processing

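The exact permutation test of list means was chosen only after the data were seen; the other alternatives were planned. No result past its threshold reversed direction. The erythrocyte (-0.0667 to 0.0466) and adipocyte (-0.1256 to 0.0641) means crossed zero with single kidneys left out and never passed. Of 112 named genes, 13 were weaker with medians aligned, 5 with the replicate block (1 stronger), 3 without a mean trend and 1 with array weights (5 stronger). Leaving out dim genes made 1 of 110 tested and 3 of 99 tested stronger at the 25th and 50th percentiles, with 2 and 13 dropped untested, and quantile normalisation 1, while all 112 kept their calls with the brightest row per gene; over all fits with a kidney left out, 101 calls of named genes were weaker and 12 stronger. Stk11 stayed lower and past the threshold throughout (-0.28 to -0.22 with each kidney left out). With quantile normalisation 1623 genes were higher and 1301 lower, and with medians aligned 1316 and 609. At adjusted p under 0.01 there were 693 and 216, and at 1.5-fold 312 and 55. Leaving out each kidney gave 1089 to 1947 higher and 435 to 1473 lower genes. The cause of these shifts was not tested, except that stricter thresholds admit fewer genes by construction.

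Values of lists are mean log2 differences. With an estimated correlation 0 lists passed, and these 20 lost their call with their means as in the fit: macrophage 0.8515, matrix 0.70, injury 0.6946, complement 0.6805, urothelium 0.3749, chemokines 0.2948, NF-kappaB 0.2545, interferon 0.173, CREB 0.162, T and NK cells 0.1256, proliferation 0.0926, LKB1 kinases 0.053, fatty acid oxidation -0.0714, cholesterol synthesis -0.0998, glycolysis -0.108, oxidative phosphorylation -0.142, proximal tubule -0.15, thick ascending limb -0.3112, distal convoluted tubule -0.3137 and intercalated cells -0.3639. Exact permutation kept 12 lists and lost 8: CREB 0.162, T and NK cells 0.1256, proliferation 0.0926, LKB1 kinases 0.053, fatty acid oxidation -0.0714, cholesterol synthesis -0.0998, glycolysis -0.108 and proximal tubule -0.15. By fry 14 lists passed (24 in either direction).

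Quantile normalisation ended the LKB1 kinase call (0.0323) and added the ciliopathy list (-0.026). Aligned medians ended fatty acid oxidation (-0.0734) and cholesterol synthesis (-0.1017). Leaving out dim genes ended T and NK cells (0.1091 at the 25th percentile, 0.0277 at the 50th), and at the 50th also proliferation (0.0804) and LKB1 kinases (0.053), while the neutrophil list had no genes left and gives no value. Array weights added endothelial markers (0.098) and ended fatty acid oxidation (-0.0547) and glycolysis (-0.0789). The brightest row per gene and the other variance priors changed no list call. Leaving out a kidney changed calls of endothelial (0.0187 to 0.0976), podocyte (0.0492 to 0.0758), adrenal (-0.0877 to -0.0475), T and NK cell (0.0961 to 0.1556), fatty acid oxidation (-0.0879 to -0.0482), cholesterol synthesis (-0.1319 to -0.0622) and glycolysis lists (-0.1379 to -0.089). The cause was not tested.

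Same-numbered controls and knockouts correlated at 0.25, 0.31, 0.10, -0.08 and 0.19 in their deviations from the group means. Pairs with different numbers ran from -0.26 to 0.24, and 3 of 5 numbers correlated best with their own. On the second principal component controls 1 to 5 lay at 12, -14.5, 10.1, -5.6 and -0.2. Knockouts 1 to 5 lay at 11.4, -7.2, 7.2, -3.1 and -10.2. The main fit did not pair the mice, but whether the numbers mark related mice or arrays stays open. The exact permutation tests shuffled the kidneys without regard to these numbers, so their p-values hold only if the numbers mark no pairs. With the replicate number as a block 1826 genes were higher and 955 lower, with the endothelial list past camera (0.0558). The planned sex covariate was not run, as all kidneys carried Y-linked signal. Signal over background limits the folds of dim genes: 7 of 113 named genes had control means below the median of negative control probe sets, and 2 also their knockout means.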

Other observations

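Some tests were chosen only after their result was seen. Among them are the scan of gene families, the per-kidney tests of families it found, and the macrophage value for the ribosomal genes. The gap tests of the intercalated and principal cell lists and the range check of the intercalated list are others. So are the tests of BMP response genes and of the region around Stk11. The intercalated and principal cell lists and their counts were planned. The short gene and copy tests of the ribosomal genes were written before their values were seen, although that family was found by the scan, and the decision on copies was tightened to use its bootstrap interval after its value was seen.

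Of 141 families of at least 15 genes by symbol, 20 passed camera, and 0 with an estimated correlation, where Rpl and Rps, Snord and Klk all had adjusted p = 0.703. Ribosomal protein genes (Rpl and Rps, with their copies) had 140 of 254 members higher and 0 lower, with a median log2 difference of 0.22. Rpl12 was higher by 0.52 (SE 0.07) and Rps15 by 0.36 (SE 0.05). Snord genes, which encode small nucleolar RNAs that guide RNA methylation, had 21 of 44 higher and 0 lower, with a median of 0.30 and Snord49a at 0.98 (SE 0.14). Of 24 Klk genes, which encode kallikrein proteases, 12 were lower and 0 higher, with a median of -0.23 (-0.26 after quantile normalisation and -0.23 with array medians aligned). Klk1, also in the distal convoluted tubule list, went from 13.69 ± 0.04 to 13.38 ± 0.17, Klk1b5 differed by -0.38 and Klk1b21 by -0.57, but this family is so alike in sequence that single members are uncertain. The genes in this paragraph were chosen after their values were seen.

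The rise of ribosomal protein and Snord genes was seen per kidney, each with exact permutation p = 0.00794. Both families were picked by the scan of these same kidneys, so that p is no independent support. The rise was also seen under both other scalings (protein-coding ribosomal genes 0.11 and 0.12, Snord genes 0.30 and 0.29). For the ribosomal protein genes, a gain of genes of short genomic span (at most 3809.5 bp) on the knockout arrays is argued against. The 438 other such protein-coding genes of like level had a median of -0.0069 (95% bootstrap interval -0.0220 to 0.00415). Transcript lengths were not compared, and this test does not cover the Snord genes. A rise carried by near-identical copies cannot be told apart: the 42 protein-coding genes had a median of 0.121 (interval 0.0942 to 0.189), which spans 0.111, the bound set at 0.5 of the family's median, with 14 higher and 0 lower against 126 of 212 copies higher. RNA of incoming immune cells may contribute, since the macrophage list had a median of 0.8655, but the level of ribosomal genes in those cells was not measured here. No test here separated these from a change in the tubules with genotype.

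Of 20 intercalated cell markers 14 fell and 1 rose, while of 23 principal cell markers 2 fell and 4 rose, although both cell types share the collecting duct. The gap between the list means (principal minus intercalated) was 0.50 ± 0.19 in knockouts, relative to the control mean (control SD 0.11, n = 5 each, exact permutation p = 0.00794, the smallest possible), and 0.50 without Car15 and Stc1 (exact p = 0.00794). The gap between the list medians was 0.386 (95% bootstrap interval over members 0.182 to 0.636). That argues against an even loss of distal nephron and collecting duct RNA as a whole. However, the thick ascending limb (-0.31) and distal convoluted tubule lists (-0.31) had means near the intercalated mean (-0.36). A loss without a shared fall of principal cell markers therefore stays open. Dilution by incoming cells would lower resident lists alike, and the gap of podocyte and endothelial lists to the intercalated list was 0.42 ± 0.15 (exact p = 0.00794), which argues against dilution as the whole cause. A change in intercalated cells with the genotype stays open: the highest knockout mean was -0.193 and the lowest control mean -0.0712, but fewer cells and lower expression per cell cannot be told apart without cell counts.

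As a hypothesis, signalling by bone morphogenetic proteins (BMPs) may be lower in knockout kidneys, where their antagonist Grem1 was the gene with the largest increase among named genes. The BMP-responsive genes Id1 (-0.83, SE 0.09) and Id4 (-1.01, SE 0.09) prompted it. A list of 12 other BMP-SMAD response genes had 5 lower and 0 higher, with camera p = 4.29e-04 (p = 0.00595 with an estimated correlation) and an exact permutation p = 0.00794 for its mean of -0.19, which was also -0.19 under both other scalings. The 5 were Id2 (-0.57), Id3 (-0.53), Smad9 (-0.45), Smad7 (-0.43) and Smad6 (-0.18), so the signal lies in the Id and Smad members and the list's median was -0.09. The list was written after values of these same kidneys were seen, so its p-values are no independent support. Camera at the preset correlation gave many lists on random splits, which kept part of the genotype difference. Among ligand genes Bmp3 (2.19, adjusted p = 4.92e-05) and Bmp2 (0.18, adjusted p = 0.0491) rose. Bmp6 (0.22), Bmp4 (0.15) and Bmp7 (-0.17) did not pass, nor did the antagonists Nog (-0.10) and Chrd (-0.05). Which way the changes in these genes bear on BMP signalling was not tested.

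Floxed alleles can carry flanking DNA of another strain, which could shift genes near Stk11. Of 361 genes within 10 Mb of Stk11, 27 were called (7.48%), against 8.04% elsewhere, an odds ratio of 0.924 (95% interval 0.599 to 1.37, Fisher's exact p = 0.770). No excess of calls was seen there. However, the controls also carried the floxed allele, on 1 or both chromosomes. Flanking DNA that both groups share gives no difference between them, so this count cannot show it.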
